A study of Mus musculus with 18 samples.

How the data were processed

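Epithelial cells were sorted from the ileum of mice, and polyadenylated RNA from the sorted cells was sequenced in bulk. Per the labels, the 18 libraries were 6 from lactating females on day 7 of lactation, 6 from age-matched virgin females and 6 from virgin males. The mice ate a breeding diet (RM3) or a maintenance diet (RM1). RNA was extracted with a column kit for small samples, and libraries were made with a directional poly(A) kit, per the labels' protocols. Sorting gates, age in weeks and sequencing batches were not given in the sources used here.

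The authors deposited 1 table per library with an Ensembl gene identifier and a raw count of reads for each gene. Per the submitters' processing notes, the tools were FastQC 0.11.5, HISAT2 2.0.4 (an aligner), featureCounts from Subread 2.0.0 and DESeq2 1.24.0, with genome build GRCm38. The annotation release, the strand setting and the treatment of reads that match several places were not given in the sources used here. Reads from a gene and an antisense or overlapping neighbour may therefore be mixed, and counts of near-identical gene copies such as Slc5a4a and Slc5a4b are uncertain. The library kit keeps strand, but whether the counting used it is not known.

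The deposited counts are whole numbers for 47729 gene identifiers in each table, and 0 rows name no gene. Symbols and GRCm38 coordinates came from the GENCODE M21 annotation, in which 47310 of the identifiers were found and 419 were not. The scaffold that holds Vamp7, Spry3 and Tmlhe was counted with the X chromosome, where the RefSeq annotation places these genes. Library totals ran from 34577104 to 49039300 counts, and 19363 to 21946 genes had a count in a library. A count of 3, taken as the floor, corresponds to 0.0612 to 0.0868 CPM (counts normalised to library size) depending on the library. Counts are of reads without molecular identifiers, so this floor covers counting error only. None of the 153 pairs of libraries matched within sampling noise: the lowest chi-square per degree of freedom was 71.3 within a group and 38.4 between libraries of different groups, so there was no sign of a duplicated library, and 18 samples were counted. This test cannot show whether libraries share an animal. The labels do not say outright that each library is a separate animal, and p-values measure the spread between these samples.

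Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 15572 genes. Libraries were scaled with TMM factors, and CPM values are on that scale. One quasi-likelihood model with a mean per group was fitted to all 18 libraries, so that the groups shared an estimate of the spread. The groups were not equally variable. The highest chi-square per degree of freedom within a group was 264.1 in virgin males, 520.5 in lactating females and 562.1 in virgin females. In the comparison of the female groups the estimate thus includes the less variable males. The comparisons were lactating female against virgin female, virgin male against virgin female, and lactating female against virgin male. P-values were adjusted by the Benjamini-Hochberg method over the 15572 genes, and a gene was called at an adjusted p under 0.05. All adjusted p-values for genes come from this edgeR test unless another tool is named. Standard errors (SE) of log2 fold changes were approximated as the absolute fold change divided by the square root of the F statistic.

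Before the data were examined, 40 gene lists were fixed: functions of the ileal epithelium, markers of its cell types and of cells outside it, and sex-linked genes. For each list, members were counted by the test over all genes and by the test adjusted over the list alone. The 37 lists with at least 3 tested members were also tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. A list score is the mean log2 CPM of the members in a library, with a prior count of 2, compared by two-sided exact permutation tests adjusted over 37 lists.

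The genes to be named were also set by a rule fixed at that stage. It took, per comparison, the 10 largest rises and the 10 largest falls among called genes. Such genes had a mean of at least 5 CPM in the higher group, all 6 libraries of 1 group on one side of the mean of the other, and a symbol that is not a predicted-gene name. It also took up to 4 members of each list by smallest p, and always Slc5a1, Slc5a4a, Slc5a4b, Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Where fewer than 20 genes qualified, all were eligible, and a gene named for 1 comparison could be given for the others. Genes outside the rule are marked as chosen after their values were seen.

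The fit was tested on simulated data made from the real means and library sizes for lactating against virgin female. Of the genes changed in the simulation, 26.9% were recovered at a fold of 1.5, 74.6% at a fold of 2 and 87.9% at a fold of 4. Among 15347 unchanged genes 5 were called. Genes were drawn independently, without the structure that real libraries share across genes, so these rates may not hold for the real data.

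Alternatives fixed in advance were DESeq2 size factors, no low-count filter or a stricter one (at least 1 CPM in 6 libraries), the DESeq2 1.42.0 test, limma voom with sample weights, the replicate number as a block, a fit of the 12 libraries compared alone, a minimum fold of 1.5, and each library left out in turn. A cell cycle score as a covariate and a fit without virgin female 2 and virgin male 6, the libraries richest in a transcript that overlaps ribosomal RNA, were chosen after seeing the data. Comparisons that share a group were set beside values from 20 simulations with no effect and from 20 splits of the shared libraries into sets of 3.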

Results

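The data describe gene expression in epithelial cells sorted from the ileum, the last part of the small intestine, of mice that were lactating, virgin and female, or virgin and male, with 6 libraries per group. Library totals were 37984403 to 46046333 counts in lactating females, 36508736 to 49039300 in virgin females and 34577104 to 47748407 in virgin males. The sex-linked genes followed the labels. Xist, the RNA that coats the inactive X chromosome, stood at 293 ± 109 CPM in lactating females and 312 ± 153 CPM in virgin females (SD, n = 6 each). It stood at 0.135 to 0.283 CPM in 5 of the 6 virgin male libraries and at 5.85 CPM in virgin male 6. The Y-linked gene Ddx3y was at 28.2 ± 2.04 CPM in virgin males (SD, n = 6) and had means of 0.00445 and 0.0164 CPM in lactating and virgin females.

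Within every group the libraries differed along the axis from crypt, where cells divide, to villus tip. The first principal component held 32.4% of the variance and rose with the cell cycle score, the mean of 35 cell cycle genes. Across the 18 libraries Pearson's r was 0.923 (permutation p = 1e-05, the smallest that 100000 permutations give) and Spearman's rho 0.895 (permutation p = 1e-05). Without the 2 libraries farthest from the median r was 0.879. Within groups r was 0.943 in lactating females, 0.974 in virgin females and 0.77 in virgin males. The component rose with the stem cell score as well (r = 0.98, rho = 0.965, permutation p = 1e-05 for both, and r = 0.972 without the 2 farthest libraries). It fell with the villus tip score (r = -0.819, rho = -0.825, permutation p = 3e-05 for both, and r = -0.758 without those 2). These 3 relations had Benjamini-Hochberg adjusted p-values of 1.5e-05, 1.5e-05 and 3e-05 for Pearson's r. A further pair of libraries stood apart: Gm42418, a transcript that overlaps ribosomal RNA, took 28910 CPM in virgin female 2 and 33520 CPM in virgin male 6, against 1372 to 4083 CPM in the other libraries.

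**Figure D1:**
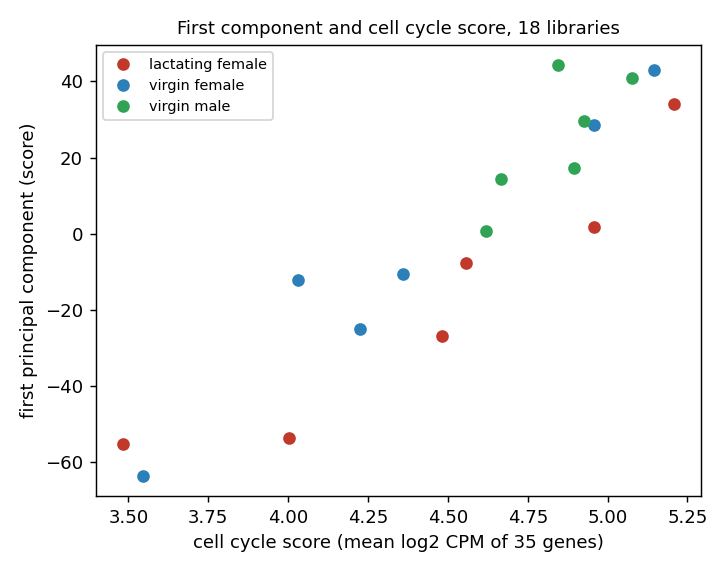
First principal component of log2 CPM (vertical axis, component score) against the cell cycle score (horizontal axis, mean log2 CPM of 35 genes) for 18 libraries, coloured by group. Libraries of all 3 groups spread along the same line (r = 0.923).

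The comparison of lactating with virgin females asks what the ileal epithelium expresses differently while mothers feed young. The called genes included 1 for calcium and 1 for iron. S100g, the calcium-binding protein calbindin-D9k of absorptive cells, rose from 2.66 ± 0.958 to 69.3 ± 79.0 CPM (SD, n = 6 each; 42.6 ± 49.9 CPM without lactating female 1), and Slc40a1, the iron exporter ferroportin, rose from 19.1 ± 4.84 to 52.7 ± 16.5 CPM. Bcl6, a transcriptional repressor, fell from 11.9 ± 2.91 to 3.06 ± 0.750 CPM, with all 6 lactating libraries below the virgin female mean. Markers of enteroendocrine cells and genes of cholesterol synthesis leaned upward as groups, which was lost with an estimated correlation (adjusted p = 0.625 and adjusted p = 0.139).

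Of 15572 genes, 9 were called: 6 rose and 3 fell, and 1003 had an unadjusted p under 0.05. The log2 fold change was -1.96 for Bcl6 (SE 0.18, adjusted p = 2.8e-05), 4.69 for S100g (SE 0.66, adjusted p = 0.00808) and 1.47 for Slc40a1 (SE 0.24, adjusted p = 0.0271). Bcl6 lies on chromosome 16 (23965052 to 23988852), S100g on chromosome X (162961992 to 162964599) and Slc40a1 on chromosome 1 (45908068 to 45926523) of GRCm38. Plod2, an enzyme that modifies collagen lysines, rose by 3.47 (SE 0.56, adjusted p = 0.0247) and was above the virgin female mean in 5 of 6 libraries. Rtn4r, a receptor for myelin proteins, rose by 1.29, Fbxl6 by 0.81 and Socs2, a feedback inhibitor of cytokine signalling, by 0.59. Dpf3, a subunit of a chromatin remodelling complex, had a log2 fold change of -0.74. Sept6, a septin chosen after its values were seen, had -0.97. The spread of S100g among lactating females was wide, and its SD exceeded its mean. Fbxl6 (chromosome 15, 76535721 to 76538746) lies directly beside Slc52a2 (76538832 to 76544608), so their counts could share reads.

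The sugar transport list, which holds the glucose transporter and sensor genes, had 0 of 9 members called over all genes and 1 adjusted over the list alone. That member was Slc5a4a, which encodes the glucose-sensing protein SGLT3a. It stood at 97.9 ± 26.1 CPM in lactating females and 42.8 ± 24.7 CPM in virgin females (SD, n = 6 each). Its log2 fold change was 1.19 (SE 0.33, adjusted p = 0.322 over all genes and 0.0155 adjusted over the list alone). All 6 lactating libraries lay above the virgin female mean, but the groups overlapped. Virgin female 1 stood at 86.9 CPM, above lactating females 2, 3 and 6 (86.4, 85.6 and 81.8 CPM). Slc5a4a lies on chromosome 10 (76147451 to 76189265), next to its close copy Slc5a4b (76057494 to 76110961). Slc5a4b was at -0.51 (SE 0.41, adjusted p = 0.918) and Slc5a1, the main glucose importer, at 0.05 (SE 0.24, adjusted p = 0.989). Reads that match both copies could be split between them.

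**Figure D2:**
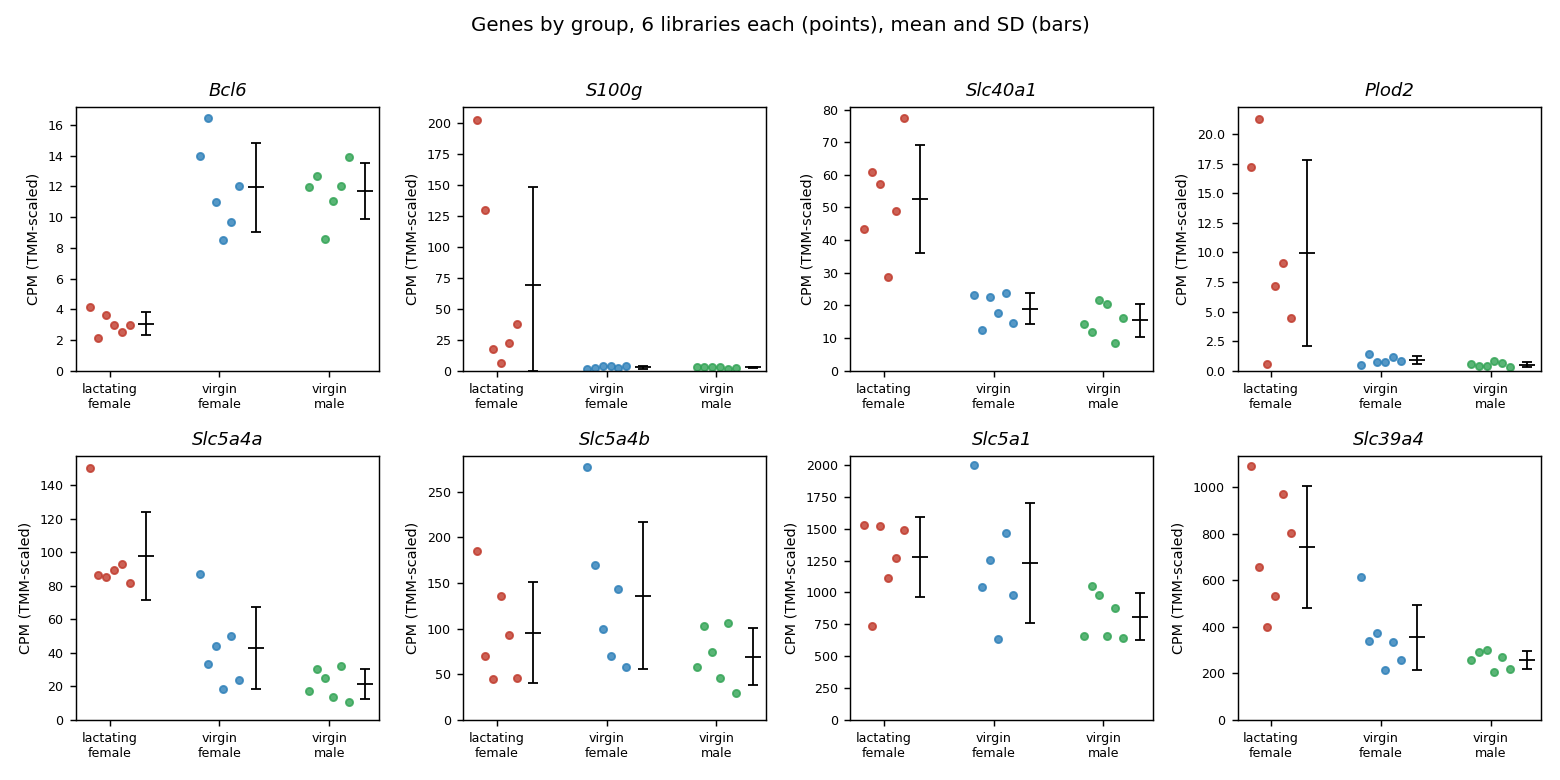
Expression of 8 genes (vertical axes, TMM-scaled CPM, each starting at 0) in 6 libraries per group (points), with mean and SD (bars, lower ends cut at 0). All 6 lactating libraries lie below the virgin female mean for Bcl6 and above it for S100g, Slc40a1, Slc5a4a and Slc39a4.

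In the list for calcium and phosphate absorption, 1 of 10 members was called over all genes and 3 were higher adjusted over the list alone. Beside S100g these were Atp2b1, the pump that moves calcium out of the cell (0.80, SE 0.15, adjusted p = 0.0522), and Cldn2, a tight junction protein (0.59, SE 0.15, adjusted p = 0.262). The list for iron and zinc had 1 of 12 members called over all genes, and adjusted over the list alone 3 were higher and 2 lower. The zinc importer Slc39a4 was at 1.06 (SE 0.25, adjusted p = 0.176) and the zinc exporter Slc30a1 at 0.72 (SE 0.17, adjusted p = 0.179). The metallothioneins, which bind zinc, lay lower: Mt1 at -1.17 (SE 0.30, adjusted p = 0.251) and Mt2, outside the naming rule and chosen after its values were seen, at -2.04 (SE 0.61). Neither list passed camera (adjusted p = 0.169 and 0.296).

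Of the hormone and STAT5 target list, 1 of 14 members (Socs2) was called over all genes and 2 adjusted over the list alone, the second being Cish, another cytokine-signalling inhibitor (0.96, SE 0.21, adjusted p = 0.141). Of the ileal bile acid genes, 0 of 8 were called over all genes, and 1 was lower adjusted over the list alone: Fgf15, the hormone the ileum sends to the liver after bile acid uptake (-1.96, SE 0.51, adjusted p = 0.292). The defence list had 0 of 14 members called over all genes and Il18, a cytokine, higher adjusted over the list alone (0.94, SE 0.23). Reg3b, an antimicrobial lectin, was at 1.45 (SE 0.54, adjusted p = 0.607) and Reg3g at 1.20 (SE 0.59).

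Camera called 5 of 37 lists, and 0 with an estimated correlation or with fry. Cholesterol synthesis leaned upward in 23 of 25 members, with a median log2 fold change of 0.21 (adjusted p = 5.07e-13, and adjusted p = 0.139 with an estimated correlation). Of its members 0 were called over all genes and 7 were higher adjusted over the list alone, among them Idi1 (0.45), Cyp51 (0.39), Sqle (0.49) and Hmgcs1 (0.30). Enteroendocrine markers leaned upward in 16 of 18 members, with a median of 0.30 (adjusted p = 6.69e-07, and adjusted p = 0.625 with an estimated correlation). None was called over all genes and 5 were higher adjusted over the list alone, led by the proglucagon gene Gcg (0.86, SE 0.20), Chga (0.54), Tac1 (1.14) and Chgb (0.74). Nuclear-encoded oxidative phosphorylation genes (adjusted p = 1.48e-06, and adjusted p = 0.942 with an estimated correlation) and cytosolic ribosomal proteins (adjusted p = 0.0149, and adjusted p = 0.942 with an estimated correlation) were called higher. The early response list, which marks stress during dissociation, was called lower (adjusted p = 0.00492, and adjusted p = 0.942 with an estimated correlation), with Hspa1a at -1.62 (SE 0.57). Markers of the proximal intestine showed S100g and Slc40a1 higher and a median of -0.27, opposite in sign to the camera direction (adjusted p = 0.6); Gata4 was at -0.36 and Cybrd1 at -0.68. The cell cycle list had a median of 0.09 (adjusted p = 0.318).

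**Figure D3:**
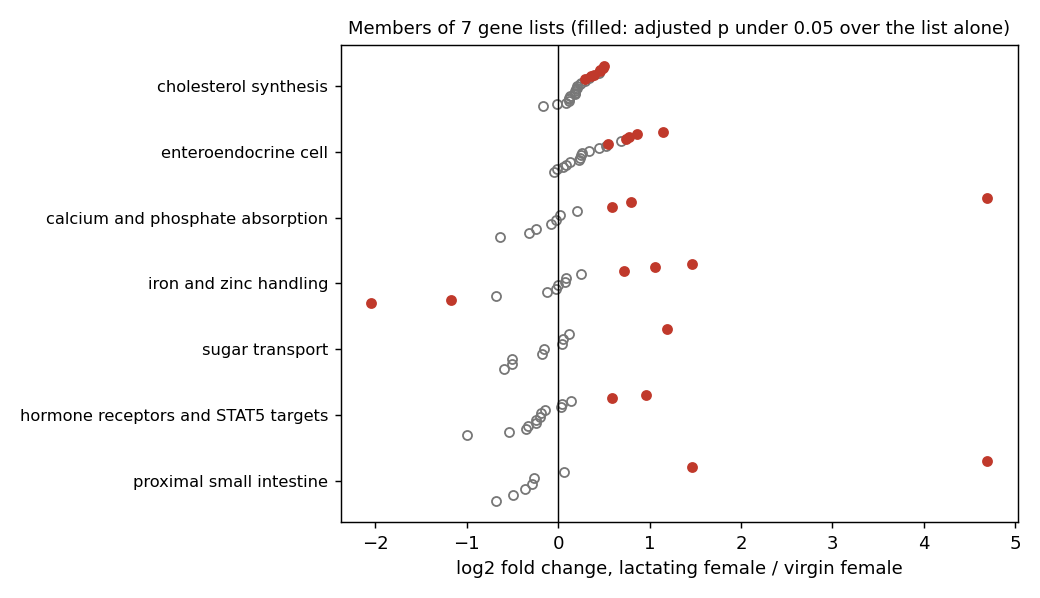
Log2 fold change of each tested member of 7 gene lists, lactating over virgin female (horizontal axis). Filled points have an adjusted p under 0.05 over the list alone, 7 of 25 for cholesterol synthesis and 5 of 18 for enteroendocrine cells.

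The number of called genes depended on the fit, and the DESeq2 test called 69 genes. The fit of the 2 female groups alone, whose estimate of the spread leaves out the males, called 1. The fit without virgin female 2 and virgin male 6 called 1, Bcl6. S100g (log2 fold changes of 3.14 to 4.70, adjusted p up to 0.268) and Slc40a1 (1.31 to 1.47, adjusted p up to 0.199) lost their calls in that fit, with voom weights, with the replicate number as a block and with the 2 groups alone, and Slc40a1 also without lactating female 1 or 6 or any 1 virgin female (1.33 to 1.54, adjusted p = 0.051 to 0.097).

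The comparison of virgin males with virgin females asks how the sexes differ outside reproduction. Beyond the sex chromosomes, Fgf15 and Nr0b2, which respond to bile acids, were lower in males. Fgf15 was at 15.6 ± 12.3 CPM in males and 123 ± 78.5 CPM in females, and Nr0b2, a nuclear receptor, at 0.412 ± 0.167 and 4.81 ± 2.64 CPM (SD, n = 6 each). All 6 male libraries lay below the female mean for both genes. For Fgf15 the groups overlapped: virgin females 1 and 5 stood at 28.2 and 33.9 CPM, below virgin male 2 at 39.4 CPM. The other males stood at 5.16 to 16.2 CPM. Brush border enzymes and fat absorption genes leaned lower in males (adjusted p = 0.279 and adjusted p = 0.365 with an estimated correlation), and cell cycle and ribosomal protein genes leaned higher (adjusted p = 0.452 and adjusted p = 0.379 with an estimated correlation).

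Of 15572 genes, 13 were called: 7 rose and 6 fell, and 11 lie on the X or Y chromosome. The Y-linked genes Eif2s3y (41.6 ± 1.96 CPM in males), Kdm5d (31.9 ± 1.86), Ddx3y and Uty (19.9 ± 0.940) were at or near the floor in females. Their adjusted p-values ran from 6.48e-15 for Eif2s3y to 7.2e-13 for Uty. Xist fell by 8.12 (SE 0.90, adjusted p = 5.91e-05). Kdm6a and Kdm5c, X-linked genes that escape inactivation, had log2 fold changes of -0.97 (SE 0.13) and -0.64 (SE 0.09). Vamp7, a vesicle fusion protein on a scaffold of the X chromosome, fell by 0.61 (SE 0.11, adjusted p = 0.0449) and lost its call in 19 of 27 alternative fits. Outside these chromosomes Nr0b2 fell by 3.53 (SE 0.63, adjusted p = 0.0296) and Fgf15 fell by 2.97 (SE 0.53, adjusted p = 0.0296). Fgf15 lies on chromosome 7 (144896531 to 144900953) and Nr0b2 on chromosome 4 (133553376 to 133556536).

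Of the ileal bile acid genes, 2 of 8 fell over all genes and the same number adjusted over the list alone. The bile acid importer Slc10a2 was at -0.53 (SE 0.32, adjusted p = 0.571) and the exporter subunits Slc51a and Slc51b at -0.39 (SE 0.20) and -0.53 (SE 0.28). The list score was 6.31 ± 0.160 log2 CPM in males and 7.26 ± 0.245 in females (SD, n = 6 each; two-sided exact permutation p = 0.00216, adjusted p = 0.0266 over 37 lists). This score includes the 2 called members, Fgf15 and Nr0b2, and was not computed without them. It therefore does not show a fall of the other members. Slc10a2, Fabp6, Slc51a and Slc51b differed by -0.384 log2 units on average (male minus female). The permutation interval of that mean ran from -0.99 to 0.22, so a fall of these transport genes was not shown. Camera on the whole list gave adjusted p = 0.000678, and adjusted p = 0.235 with an estimated correlation.

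**Figure D4:**
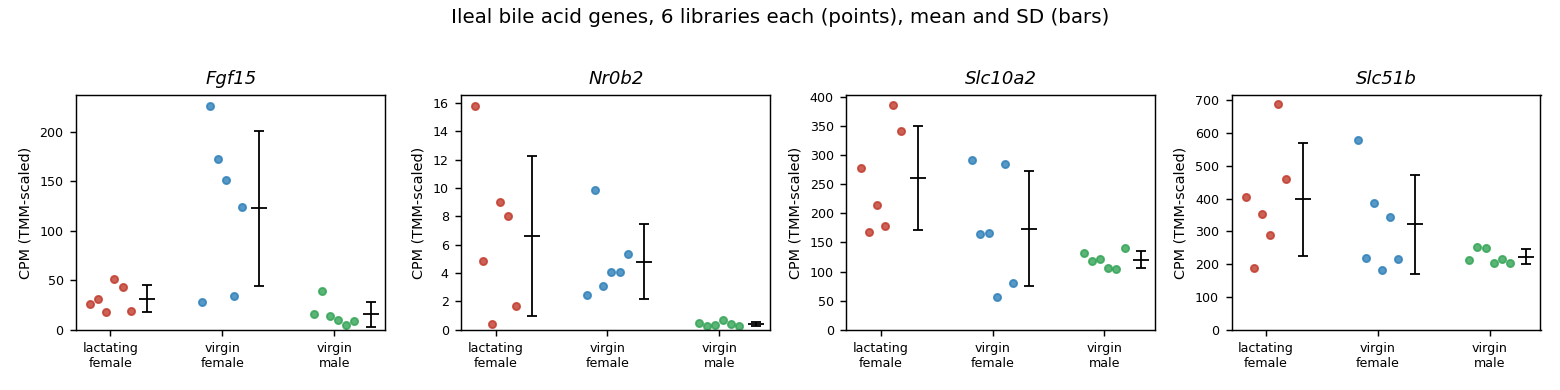
Expression of 4 ileal bile acid genes (vertical axes, TMM-scaled CPM, each starting at 0) in 6 libraries per group (points), with mean and SD (bars, lower ends cut at 0). All 6 male libraries lie below the virgin female mean for each of the 4 genes.

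Camera called 17 of 37 lists, and with an estimated correlation only the Y and the X lists held (adjusted p = 4.43e-07 and 0.00167). Brush border enzymes leaned lower in 16 of 16 members (median -0.60, adjusted p = 5.84e-10, and adjusted p = 0.279 with an estimated correlation). None was called over all genes and 9 were lower adjusted over the list alone, such as Xpnpep2 (-0.88), Ace (-1.03), Anpep (-0.81) and Dpp4 (-0.69). Fat absorption genes leaned lower in 23 of 23 members (median -0.54, adjusted p = 4e-09, and adjusted p = 0.365 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone; Fabp1 was at -1.29 (SE 0.46), Fabp2 at -0.98 and Abcg8 at -0.54. Of the sugar transport genes 0 of 9 were called over all genes and 7 were lower adjusted over the list alone, with Slc2a2 at -1.11, Slc5a4a at -0.995 (SE 0.33), Slc5a4b at -0.98 and Slc5a1 at -0.60 (camera adjusted p = 7.54e-05, and adjusted p = 0.279 with an estimated correlation). Of the amino acid and peptide transporters 0 of 16 were called over all genes and 8 were lower adjusted over the list alone, among them Slc15a1 (-0.88) and Slc16a10 (-0.76) (camera adjusted p = 2.21e-05, and adjusted p = 0.235 with an estimated correlation). The mitochondrially encoded genes leaned lower (median -0.35, with mt-Nd2 at -0.37, adjusted p = 1.23e-07, and adjusted p = 0.279 with an estimated correlation).

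In the same libraries all 35 cell cycle genes leaned higher in males (median 0.36, adjusted p = 3.83e-10, and adjusted p = 0.452 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Cytosolic ribosomal proteins leaned higher in 78 of 79 members (median 0.30, adjusted p = 6.55e-22, and adjusted p = 0.379 with an estimated correlation) and stem cell markers in 13 of 15 (median 0.26, adjusted p = 0.0037, and adjusted p = 0.657 with an estimated correlation). Fgf15 and Nr0b2 were no longer called without virgin female 2 and virgin male 6 (log2 fold changes of -2.58 and -3.10, adjusted p = 0.289 for both). Nr0b2 also lost its call with voom weights (-3.29), the replicate block (-3.655) and the cell cycle score as a covariate (-3.23), and without virgin female 2 (-3.20) or any 1 virgin male library (-3.76 to -3.43), and Fgf15 with the 2 groups alone (-2.97) and without virgin female 2 or 3 or virgin male 1, 3, 4, 5 or 6 (-2.99 to -2.71).

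The comparison of lactating females with virgin males differs in both sex and reproductive state, and neither can be separated within it. Slc5a4a rose to 97.9 ± 26.1 CPM from 21.5 ± 8.83 CPM (SD, n = 6 each; log2 fold change 2.19, SE 0.34, adjusted p = 0.00208), with all 6 lactating libraries above the male mean. S100g rose by 4.71 (SE 0.66, adjusted p = 9.56e-04), Slc40a1 by 1.76 (SE 0.25, adjusted p = 8.63e-04) and Slc39a4 by 1.53 (SE 0.25, adjusted p = 0.00303). Bcl6 fell by 1.93 (SE 0.18, adjusted p = 4.97e-06).

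Of 15572 genes, 119 were called, of which 98 rose and 21 fell, and 101 lie on autosomes. Among the largest rises were Nr0b2 (3.99, SE 0.64, adjusted p = 0.00268), Plod2 (4.25, SE 0.59), the steroid hydroxylase Cyp3a44 (3.24, SE 0.54) and the tyrosine-degrading enzyme Tat (2.87, SE 0.66). Acta1, an actin of muscle, rose by 2.90, the glycosyltransferases Gcnt1 and Fut2 by 2.90 and 2.60, and the metal exporter Slc30a10 by 2.5 (SE 0.38, adjusted p = 0.00199). Apart from Bcl6 and the Y-linked genes, the falls named by the rule were -0.99 for Ces1e, -0.96 for Pter, -0.87 for the glycine transporter Slc6a9, -0.66 for the cold-induced Rbm3 and -0.64 for Mreg.

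Of the sugar transport genes 1 of 9 rose over all genes and 3 adjusted over the list alone. Slc5a1 was at 0.66 (SE 0.24, adjusted p = 0.218) and Slc5a4b at 0.47 (SE 0.41, adjusted p = 0.548). Of the calcium genes 2 of 10 rose over all genes (S100g and Atp2b1, at 1.003), and of the iron and zinc genes 3 of 12 (Slc40a1, Slc39a4 and Slc30a1, at 1.08); adjusted over the list alone, 4 rose and 1 fell in each. Camera called the sugar list (adjusted p = 0.00688, and adjusted p = 0.517 with an estimated correlation) and the iron and zinc list (adjusted p = 0.00823, and adjusted p = 0.447 with an estimated correlation), and the calcium list had adjusted p = 0.157. The calcium list score was 5.91 ± 0.331 log2 CPM in lactating females and 5.47 ± 0.063 in males (SD, n = 6 each; two-sided exact permutation p = 0.00216, adjusted p = 0.02 over 37 lists), and 5.989 and 5.924 without S100g (two-sided exact permutation p = 0.494). The proximal intestine score was 5.56 ± 0.529 and 4.75 ± 0.328 (two-sided exact permutation p = 0.00649, adjusted p = 0.048), and 5.605 and 5.456 without S100g and Slc40a1 (two-sided exact permutation p = 0.623). Among the bile acid genes 1 of 8 rose over all genes and 6 adjusted over the list alone, with Slc10a2 at 1.11 (SE 0.32). The hormone list had 2 of 14 members higher over all genes, Cish (1.48, SE 0.21, adjusted p = 9.78e-04) and Socs2 (0.48), and 3 higher and 2 lower adjusted over the list alone. Gcg rose by 0.90 (adjusted p = 0.046), 1 of 18 enteroendocrine markers over all genes against 5 adjusted over the list alone, and lost its call in 16 of 27 alternative fits. Il18 rose by 1.32 (SE 0.23, adjusted p = 0.0063), and Reg3b was at 1.82 (adjusted p = 0.142). Of the immune cell markers 0 of 7 were called over all genes and 3 were higher adjusted over the list alone (Csf1r at 1.28, Gzma at 2.09 and Igkc at 1.48), and Vim, 1 of 2 tested mesenchymal markers, rose by 0.87. Camera called 22 of 37 lists, and 2 with an estimated correlation, the Y and the X lists. Brush border enzymes leaned higher in 15 of 16 members (median 0.56, adjusted p = 1.7e-05, and adjusted p = 0.517 with an estimated correlation). Cell cycle genes leaned lower in lactating females in 35 of 35 members (median -0.28, adjusted p = 1.7e-05, and adjusted p = 0.595 with an estimated correlation). The DESeq2 test called 410 genes, and the fit without virgin female 2 and virgin male 6 called 61.

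Lactating females differed the same way from both virgin groups in 7 genes. S100g, Slc40a1, Plod2, Fbxl6, Rtn4r and Socs2 rose and Bcl6 fell in both tests, and 6 of the 7 are autosomal. Both comparisons use the same lactating libraries. In 20 simulations with no effect the highest overlap was 0, and independent lists of these sizes would share 0.0378 higher and 0.00405 lower genes. These values are no fair baseline: the simulations lack the crypt and villus structure of the libraries, and the tests are not independent. Among other splits of the real female libraries the highest overlap was 2346. With the lactating libraries split into sets of 3, the overlap had a median of 2.5 over 20 splits and ran from 1 to 8.

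The lactation and the sex fold changes, both taken against virgin females, had a Pearson's r of 0.134 across 15043 genes outside the sex chromosomes. Genes are not independent replicates, and the shared virgin females alone gave r = 0.5 in simulations with no effect. The positive r is therefore no sign of a common change. The covariance was 0.014 against 0.039 in the simulations. With the virgin females split into sets of 3, r averaged -0.271 and ran from -0.558 to -0.027, so it was negative in every split.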

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

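The tests of this part were chosen after the results they bear on had been seen, except that of crypt and villus share for the absorptive genes in males, which was set down before its result. The threshold for regrouped libraries was fixed, but it was set down for these counts after most of them had been seen.

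Over 361 sets of 6 libraries, 19 had a library far from the other 5, and chance would give about 18 if the sets were independent. They come from the same libraries and are related, so this number is rough. Single cases carry little weight, but virgin male 6 stood apart in several sets. Virgin male 6 had 5.85 CPM of Xist (others 0.135 to 0.283), 37.7 CPM of Eif2s3y (others 41.5 to 43.2), 23.5 CPM of Vamp7 and 78.1 CPM of Fabp1, and an X-linked list score of 5.67. Its Gm42418 was at 33520 CPM and its Rn7sk at 687.5 CPM (others 7.502 to 12.48). Virgin female 2 had 28910 CPM of Gm42418 and a circadian clock score of 4.69 (others 3.85 to 4.08). Lactating female 1 had 151 CPM of Slc5a4a (others 81.8 to 93.2), 129 CPM of Slc2a2, 5.42 CPM of Slc19a3 and an endothelial score of -0.672. Lactating female 5 had 29.8 CPM of Kdm6a, and virgin female 4 had 3.73 CPM of Tac1. Scores of lists also stood apart for colon in virgin male 2 (5.16), goblet cells in virgin female 1 (7.12), immune cells in virgin male 4 (-0.209) and the Y chromosome in virgin female 3 (-3.56, where all members are near the floor).

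Few regroupings of the libraries called as many genes as the real groups, which makes chance less likely but does not exclude it. The 100 splits are a sample of 462 possible ones. Splits that mix the groups also carry any real difference in their spread, which lowers their counts. The count of 13 in males cannot be judged this way, since 11 of its genes lie on the X or Y and are fixed by sex. For lactating against virgin females 3 of 100 splits called at least 9 genes, the real one included, and the highest other split called 2687. For males against virgin females 2 of 100 splits called at least 13 (highest other 1035), and outside these chromosomes 2 of 100 called at least 2 (highest other 1004). For lactating females against males 2 of 100 called at least 119 (highest other 160) and 2 of 100 at least 101 outside the X and Y (highest other 157), and for the 7 genes shared by both lactation tests 3 of 100 gave as many (highest other 2346). A split that calls so many genes points to a structure of the samples. In the split with 2687 genes the sets differed by 52.8 on the first principal component, the axis of cell cycle and stem cell genes, against 11.3 in the real one. Lactating females and males lay nearly as far apart on that axis (42.4) as the sets of the split with 160 genes (44.3; median of the other splits 11.9), and males and virgin females differed by 31 (49.9 in the split with 1035 genes; median 13.6). Chance could account for the list counts in 2 comparisons. For lactating against virgin females 98 of 100 splits called at least the 5 lists (highest other 20). For males against virgin females 32 of 100 called at least the 17 (highest other 24), and 40 of 100 at least 15 without the X and Y lists (highest other 22). For lactating females against males 4 of 100 called at least 22 (highest other 22), and without the X and Y lists 4 of 100 called at least 20 (highest other 22).

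The first pattern is the rise of Slc5a4a, S100g, Atp2b1, Cldn2, Slc40a1, Slc39a4 and Slc30a1 in lactating females, the members of the sugar, calcium and metal lists that were higher adjusted over the list alone. With the cell cycle score as a covariate their median log2 fold change was 1.14, against 1.06 without it. This score hardly differed between the groups (4.448 and 4.377 log2 CPM, two-sided exact permutation p = 0.835). The scores thus give no sign of a different share of dividing cells. The covariate could move the fold changes little, so this test cannot decide on the share of crypt and villus cells. A more proximal sampling site is argued against, since the other 6 proximal markers differed by -0.36. Their 95% permutation interval ends at 0.22, below the smallest rise of 0.59. For few libraries, genes were chosen anew from the 3 lists with 1 lactating and 1 virgin female library left out. All 6 lactating libraries lay above the left-out virgin females, by medians of 0.62 to 1.306 log2 units. The rise was thus not confined to single lactating libraries. The 3 lists and the direction had been picked with all libraries, and 6 to 8 genes were chosen each time. The left-out libraries were therefore not independent, and the test cannot exclude this explanation. A response to lactation is a candidate explanation that stays open as a hypothesis. Crypt and villus share, few libraries, diet, which the labels do not assign to groups, and reads shared by Slc5a4a and Slc5a4b stay open beside it.

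The second pattern is the downward lean of 64 absorptive genes in virgin males, negative in 60, with a median log2 fold change of -0.56; none was called over all genes, and the 4 lists lost their calls with an estimated correlation (adjusted p = 0.235 to adjusted p = 0.365). A larger share of crypt cells in the male libraries is consistent with the test set beforehand: with the cell cycle score as a covariate the median was -0.18. The libraries rich in ribosomal RNA are not the whole cause, since without them the median was -0.41. Whether crypt share differs between the sexes or between preparations was not tested, and no biological explanation is put forward.

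The third pattern is the lower Fgf15 and Nr0b2 in virgin males. For Fgf15, virgin females 1 and 5 (28.2 and 33.9 CPM) lay below virgin male 2 (39.4 CPM) but above the other males (5.16 to 16.2 CPM). Lactating females stood at 17.7 to 51.4 CPM, also above those other males. The remaining virgin females stood at 124 to 226 CPM, so the size of the mean difference in Fgf15 depends on them. Crypt share is argued against as the whole cause, since with the covariate Fgf15 was at -3.01 (SE 0.56, adjusted p = 0.0494) and Nr0b2 at -3.23 (SE 0.62), against -2.97 (SE 0.53) and -3.53 (SE 0.63) without it; the call of Nr0b2 ended (adjusted p = 0.0611), and with the fold of the fit without the covariate in place of the smaller one its adjusted p would be 0.0271. A less distal sampling site is argued against only for a large shift. Slc10a2, Fabp6, Slc51a and Slc51b differed by -0.38 on average, with a permutation interval whose lower end was -0.99, above the bound of -1.49. That bound was derived from the Fgf15 fold change, and how steeply these genes change along the ileum was not measured. A smaller shift stays open, since the mean lay on the same side. A large shift in time of day is argued against: over 15 clock genes the largest fold change plus 2 SE was 1.09, and 0 passed adjusted over the list alone. Beside a smaller shift in sampling site, feeding state, which moves Fgf15 and Nr0b2 and was not given in the labels, and sex itself stay open as untested explanations.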

How the results depend on the processing

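The cell cycle covariate and the fit without virgin female 2 and virgin male 6 were chosen after seeing the data, and where a value moved the cause was not tested. For lactating against virgin females the count of 9 genes became 69 with the DESeq2 test, 15 with the stricter filter, 2 with voom weights, 1 with the 2 groups alone, 61 with the covariate and 1 without the libraries rich in ribosomal RNA. It ran from 2 to 16 with a library left out. It was 2 without lactating female 1 or virgin female 1, 2 or 3, 3 without lactating female 6 or virgin female 4 or 5, 5 without virgin female 6 or virgin male 1, 2, 3, 4 or 6, and 16 without lactating female 3. For males against virgin females 13 became 20 without a filter, 30 with DESeq2 and 20 with voom, and 10 to 18 with a library left out. For lactating females against males 119 became 410 with DESeq2, 217 with voom and 61 without the rRNA-rich libraries. It ran from 62 to 311 with a library left out: 311 without lactating female 2, 73 and 71 without lactating female 1 and 6, and 68, 69, 76, 65 and 62 without virgin male 1, 2, 3, 4 and 6. The 7 shared genes became 11 with the stricter filter, 51 with DESeq2, 2 with voom, 43 with the covariate, 1 without the rRNA-rich libraries and 2 to 14 with a library left out (14 without lactating female 3).

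The correlation of 0.134 became 0.425 without a filter. With a library left out it ran from -0.018 (without lactating female 2) to 0.304 (without virgin female 4), and it was 0.3 without lactating female 1. The list counts of 5, 17 and 22 became 0, 2 and 2 with an estimated correlation and 0, 2 and 4 with fry. The first became 3 without the rRNA-rich libraries and ran from 3 to 11 with a library left out (10 without lactating female 1, 11 without virgin female 4), the others from 16 to 22 and 17 to 24. Bcl6 kept its call in every fit. S100g lost its call against virgin females with voom (3.14), the replicate block (4.08), the 2 groups alone (4.70) and without the rRNA-rich libraries (4.62). So did Slc40a1 (1.31, 1.46, 1.47 and 1.37), and without lactating female 1 or 6 or any 1 virgin female (1.33 to 1.54). Nr0b2 lost its call in males with voom (-3.29), the block (-3.655) and the covariate (-3.23), and Fgf15 with the 2 groups alone (-2.97). Over 27 alternative fits the calls lost most often among named genes were those of Socs2 and Sept6 (20 each), Fbxl6 (18), Rtn4r (17), Slc40a1 (12), Plod2 (11) and Dpf3 (9) against virgin females, Vamp7 (19), Nr0b2 (11) and Fgf15 (9) in males, and Tat (19), Socs2 and Gcg (16 each), Rfk (15), Pter (14), Fut2 and Slc52a3 (13 each), Rbm3 (12), Slc19a3 (11), Slc6a9 (10) and Gcnt1 (8) in lactating females against males. Slc5a4a was called against virgin females only with the covariate (1.40, adjusted p = 0.0122; range over the alternatives 0.0122 to 0.612). Signs turned for Slc5a4b against males with the covariate (-0.022) and for Slc5a1 against virgin females with a library left out (range -0.081 to 0.246).

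Replicate numbers gave no clear sign of pairing: 7 of 18 same-number correlations were over 0.1 (-0.219 to 0.477, mean 0.083), and 5 libraries correlated best with their own number. No chance value was computed for these counts, so pairing or a batch shared by number is not excluded. With the replicate block 1 gene was called for lactating against virgin females, 11 for males, 114 for lactating females against males, and 1 was shared. Depth limits rare transcripts, since 3 counts correspond to 0.0612 to 0.0868 CPM. At a fold of 1.5, 26.9% of simulated changes were recovered at the real library sizes; other depths were not simulated.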

Other observations

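The test of solute carriers was chosen after its result had been seen; the tests within groups were set down before.

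Outside the fixed lists, some further genes were called higher in lactating females than in virgin males; those named here were chosen after their values were seen and were not tested as a group. The copper importer Slc31a1 rose to 561 ± 207 CPM from 189 ± 29.2 CPM (SD, n = 6 each; log2 fold change 1.57, SE 0.21, adjusted p = 5.28e-04), in 6 of 6 libraries. The riboflavin transporters Slc52a2 and Slc52a3 rose by 1.06 (SE 0.22) and 1.09 (SE 0.24), and riboflavin kinase, Rfk, by 0.99 (SE 0.23, adjusted p = 0.0479). The transporter Flvcr2 rose by 2.42 (SE 0.40, adjusted p = 0.00345). The thiamine transporter Slc19a3 had 2.87 (SE 0.61) from a level of 0.197 CPM, but lactating female 1 stood at 5.42 CPM and the others at 0.556 to 0.953 CPM. The call of Slc19a3 was lost in 11 of the 25 alternative fits that tested it, the fit without lactating female 1 among them. Slc52a2, Slc52a3 and Rfk lost their calls in 7, 13 and 15 of 27 alternative fits (adjusted p up to 0.147). Against virgin females none of these was called: Slc31a1 was at 0.98 (SE 0.21, adjusted p = 0.113), Slc52a2 at 0.504 (adjusted p = 0.717), Rfk at 0.33 and Slc52a3 at 0.26. In the fit with the cell cycle score, chosen after seeing the data, Slc31a1 (0.98, adjusted p = 0.00172) and Slc52a2 (0.568, adjusted p = 0.00569) were called against virgin females as well.

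Interferon response genes leaned higher in lactating females than in males, with 0 of 17 called over all genes and 8 higher adjusted over the list alone (camera adjusted p = 1.7e-05, and adjusted p = 0.517 with an estimated correlation). Against virgin females the median was 0.24 (adjusted p = 0.152). In the comparison with males the immune cell markers moved the same way: 6 of 7 had positive fold changes (median 1.164, camera adjusted p = 0.231) and 3 were higher adjusted over the list alone (Csf1r at 1.28, Gzma at 2.09 and Igkc at 1.48), while Ptprc was at 0.247 CPM in lactating females and 0.240 CPM in males. Trpv6, an intestinal calcium channel also chosen after its values were seen, had 0 counts in every library, which at 3 counts allows up to 0.0868 CPM.

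A hypothesis is that solute carriers as a family are higher in lactating females than in virgin males. Of the 98 genes that rose, 11 (11.2%) were solute carriers, against 263 of 15572 tested genes (1.7%; one-sided Fisher's exact p = 7.92e-07), and 1 solute carrier fell. In the same comparison cell cycle genes leaned lower in lactating females in 35 of 35 members, stem cell markers lower in 14 of 15 and brush border enzymes higher in 15 of 16, with 0 called over all genes or over the list alone (adjusted p = 0.595, adjusted p = 0.537 and adjusted p = 0.517 with an estimated correlation). With the cell cycle score as a covariate 13 of 105 risen genes were solute carriers (one-sided Fisher's exact p = 2.37e-08), 10 of the 11 among them. Both tests count genes as independent and use the libraries in which the family was noticed, so these p-values only describe the share. Whether the larger share follows sex or lactation stays open. Against virgin females all 11 had positive fold changes (0.26 to 1.939). Of these, 1 (Slc40a1) was called in the main fit and 7 with the cell cycle score as a covariate. The 11 were selected as high in the same lactating libraries, so their positive signs were partly built in.

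A further hypothesis was that zinc status ties Mt1 to Slc39a4 in every group. After removing group means, Pearson's r over 18 libraries was 0.027 (permutation p = 0.908) and Spearman's rho -0.051 (permutation p = 0.848), and r was 0.216 without the 2 libraries farthest from the median. The groups went opposite ways (r = -0.394 in lactating females, 0.735 in virgin females and -0.396 in virgin males, 6 libraries each), so a relation in every group was not found. For Bcl6 and Cish, which could share a STAT5 signal, r was 0.15 (permutation p = 0.608), rho was 0.201 (permutation p = 0.475) and r without the 2 farthest libraries was 0.099 (within groups 0.225, -0.019 and 0.596 in the same order), so the negative relation was not found either. Over these 2 relations the adjusted p was 0.908 for r and 0.848 for rho in both.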
